A study of Saccharomyces cerevisiae with 18 samples.

How the data were processed

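The samples were 18 TIF-Seq libraries of wild-type diploid yeast. Per the labels, RNA was made into full-length cDNA of capped and polyadenylated molecules, which was circularised, fragmented and sequenced across the joined ends. The submitters' processing notes name CASAVA, Novoalign 2.07.10 and the genome build R64. The deposited values are counts: whole numbers of reads for each pair of a 5' and a 3' position, which the authors summed over the libraries of each kind, per the file headers and the accompanying note. The table holds 2502656 pairs, 502140 of which have no read in any of the 6 columns used, and spans from 40 to 5000 nt; a filter on span is not given in the sources used here. Whether duplicate reads were collapsed to molecules is likewise not given in the sources used here, so values are called reads, and PCR copies may be counted more than once. All count columns were used and 0 were left out.

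Positions were checked against the R64 reference and its annotation: every position lay within its chromosome. A read was assigned to a protein-coding gene when it covered the whole coding sequence on its own strand and no other. Reads covering 2 or more coding sequences, lacking the 5' part, the 3' part or both, lying on the opposite strand or overlapping none formed 6 further classes. Of 6002 protein-coding genes, 338 have a near-identical copy, found with blastn 2.17.0 as a match of at least 90% identity over at least 80% of the length, and their counts are uncertain. The length ran from start to stop codon with introns included. Copies of intron-containing genes could therefore be missed, and a gene without a listed copy may still have one.

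Because libraries are summed within a column, the tests planned for replicates could not be run. This holds for the edgeR quasi-likelihood test, the DESeq2 Wald test, gene set tests, exact permutation tests, fits with a block, and leaving out each replicate or preparation. The rules used in their place were set after it was seen that columns were pooled and before gene values were seen. A gene counted as measured with at least 20 reads per protocol, summed over media. It was called higher or lower in galactose when the ratio was at least 2-fold in the standard and in the long-enriched protocol and both 95% intervals excluded 1. All long-enriched libraries come from cultures that are also in the standard columns, so they repeat the measurement technically and are not biological replicates. The standard galactose column sums cultures 1, 2, 3 and 4, and the long-enriched one only 1 and 4. Differences between protocols in galactose can therefore include differences between cultures. Ratios were scaled with the trimmed mean of M values of edgeR 4.0.16 in R 4.3.3, with size factors of DESeq2 1.42.0 as an alternative. Intervals are exact Poisson ratio intervals for reads, exact binomial or Wilson intervals for shares, and cover counting error only. The isoform difference alone has a bootstrap interval over genes. Log2 ratios used 0.5 reads as pseudocount. Folds against 0 reads were computed with the 0 set to a floor of 3 reads, and the lower limit of the 95% interval is given beside each.

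Genes were named by fixed rules. The 10 highest and 10 lowest by standard log2 ratio were taken among genes with a mean CPM of at least 10 and both intervals excluding 1, with all members of the galactose and Gal4 lists and up to 4 called members of every other list, or the 2 most abundant members as values. For UTRs the 5 largest shifts each way were named, for isoforms the 5 genes with the most and the fewest, and for the protocols 5 genes each way with reads in all 4 capped columns. HXT7 and PYK2, the gene groups of the class comparison, the multi-gene examples and the genes named for the non-capped control were chosen after their values were seen. The 18 gene lists were fixed before the data were examined.

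A UTR length was the distance from the read's end to the start or stop codon, called shifted at 20 nt or more in the same direction in both protocols with at least 20 reads in each of the 4 capped columns. Reads of both media were also dealt at random to them 20 times. Isoforms per gene were the expected number of distinct pairs among 50 reads. Spans and classes were computed over reads. The 5' ends of the control were compared with the gene's most used capped 5' end in windows of 50 nt. The gene rule was tested on simulated data, with counts drawn with counting error alone for 3544 genes of which 200 were changed 4-fold; 180 were recovered (90%) and 0 unchanged genes were called. Differences between cultures were not part of that simulation. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9.

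Alternatives were other scalings, no minimum of reads, reads overlapping at least 50% of a coding sequence, pairs seen at least 2 times, other minima, medians, a limit of 500 nt on UTRs, a depth of 200 reads, bins of 5 nt, all molecules or distinct pairs, and windows of 20 and 100 nt. Scaling by total reads, each protocol alone, subtraction of carry-over and removal of genes with a given site were added after the data were seen.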

Results

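Transcript isoform sequencing (TIF-Seq) reads the capped 5' end and the polyadenylated 3' end of the same RNA molecule, so that each molecule is placed on the genome as a pair of ends. It was applied to diploid Saccharomyces cerevisiae of the S288c background in exponential growth on rich medium with glucose or with galactose. The 18 libraries comprised 6 standard libraries from 2 glucose cultures, 6 standard libraries from 4 galactose cultures, 2 libraries per medium made with a modification that enriches for long molecules, and 1 library per medium made from polyadenylated molecules without a cap. The deposited table sums the libraries of each kind into 6 columns of read counts. No spread between replicates could therefore be computed, and no p-value is given. All intervals below are 95% intervals that cover counting error only, except the bootstrap interval over genes for the isoform difference. The counting intervals and the random deals of reads treat each read as independent. If PCR copies are among the reads, these intervals are too narrow and the deals give too few shifted genes. The standard columns held 6290819 reads in glucose and 6425269 in galactose, the long-enriched columns 2745847 and 3559614, and the non-capped columns 1317650 and 1100551. Coordinates are those of build R64, and gene positions are of the coding sequence from start to stop codon.

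The first comparison asked which genes differ between cells grown on galactose and on glucose. Among genes with a mean CPM of at least 10 and both intervals excluding 1, GAL1, GAL10, GAL2 and GAL7 had the highest standard log2 ratios. GAL1 (YBR020W, chromosome II, 279021 to 280607), galactokinase, had 0 standard reads in glucose and 24292 in galactose. With the 0 set to 3 reads it was 5823-fold higher (lower limit of the interval 4735). GAL10 (YBR019C, chromosome II, 276253 to 278352), the epimerase and mutarotase of the pathway, had 0 and 4863 standard reads, in the same way 1166-fold higher (lower limit 947.6). GAL7 (YBR018C, chromosome II, 274427 to 275527), the uridylyltransferase, had 0 and 2922, in the same way 700.4-fold higher (lower limit 569). GAL2 (YLR081W, chromosome XII, 290212 to 291936), the galactose permease, had 1 and 14251 reads. Its ratio was 10248, with an interval from 1839 to 404800.

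The regulators and the remaining member of the pathway were higher by smaller factors. GAL3 (YDR009W, chromosome IV, 463434 to 464996), the inducer that binds galactose, was 423-fold higher in the standard protocol (interval 117 to 3498) and 263-fold higher in the long-enriched one (177 to 411). PGM2 (YMR105C, chromosome XIII, 475897 to 477606), the major phosphoglucomutase, was 23.2-fold higher (16.7 to 33.3) and 24.6-fold higher (22.4 to 27.1) in the same order. GAL80 (YML051W, chromosome XIII, 171594 to 172901), the repressor of Gal4, was 3.84-fold (2.90 to 5.18) and 2.82-fold (2.43 to 3.28) higher. GAL4 (YPL248C, chromosome XVI, 79711 to 82356), the activator itself, had 0 and 8 standard reads and 8 and 36 long-enriched reads, too few in the standard columns to be measured. In the long-enriched glucose column GAL1 had 77 reads, GAL2 48, GAL10 16 and GAL7 3, so the long-enriched ratios of these genes were lower, from 85.2 for GAL7 to 1333 for GAL1. Those reads, and the ratios without them, are taken up again in the closing section.

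Over the genome 3581 genes had at least 20 reads in each protocol. Of these, 224 were at least 2-fold higher in galactose in both protocols with both intervals excluding 1, 91 were at least 2-fold lower, and 3266 were neither. Across genes the log2 ratios of the protocols had a Pearson correlation of 0.83 and a Spearman correlation of 0.68, and the median absolute difference between them was 0.30; genes are not independent replicates, and every long-enriched library shares its culture with the standard column. For 16 of the 70 measured genes named by rule the intervals of the protocols did not overlap, so a fold given for 1 protocol is not that of the other. Ratios are relative to trimmed-mean scaling. Scaling by total reads moved the median log2 ratio by 0.48 in the standard and 0.15 in the long-enriched protocol, and gave 348 genes higher and 56 lower. The share of calls that were higher was 71.1% under trimmed-mean scaling and 86.1% under total scaling.

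**Figure D1:**
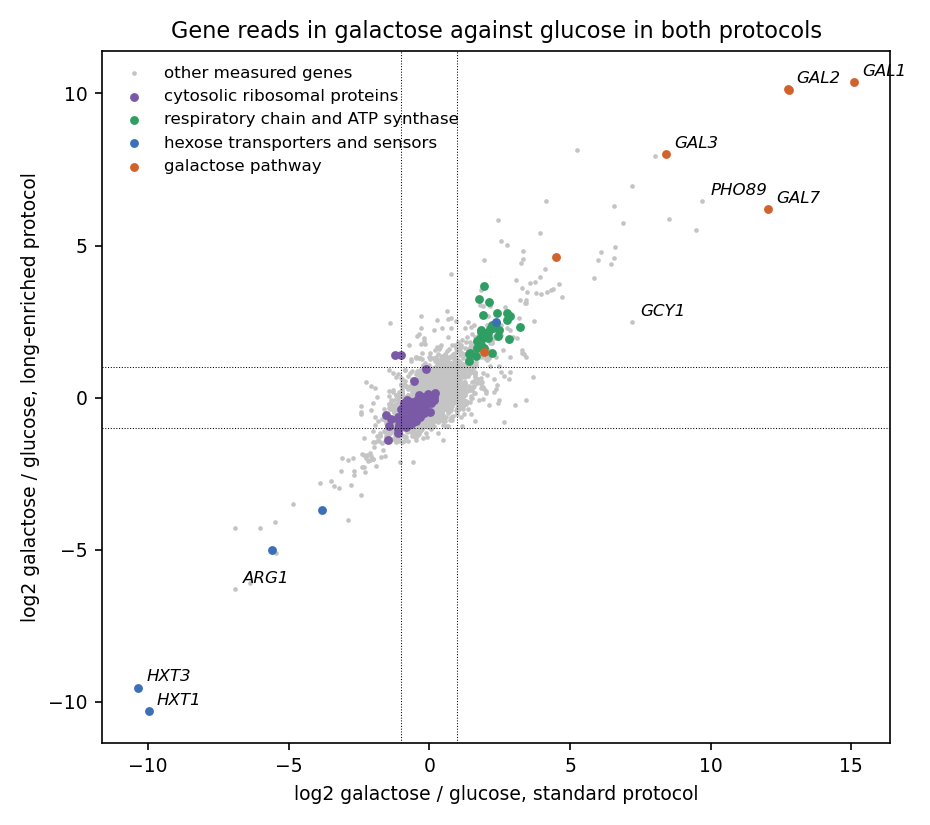
Log2 ratio of galactose over glucose reads per gene, standard protocol on the horizontal and long-enriched protocol on the vertical axis, for the 3581 measured genes, each point a gene and dotted lines at 2-fold. Galactose pathway genes (orange) lie at the upper right and HXT1 and HXT3 (blue) at the lower left, with log2 ratios of -9.98 and -10.35 in the standard protocol.

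Among the other genes at the upper end, PHO89 (YBR296C, chromosome II, 796798 to 798522), a sodium and phosphate cotransporter, had 0 standard reads in glucose and 575 in galactose. With the 0 set to 3 reads PHO89 was 137.8-fold higher (lower limit 111.7), and it was 88.9-fold higher (67.6 to 120) in the long-enriched protocol. SDD1 (YEL057C, chromosome V, 45020 to 45721) had 0 and 493 standard reads covering it, 118.2-fold higher with the 0 set to 3 reads (lower limit 95.7). SDD1 was 53.6-fold higher (18.1 to 262) in the long-enriched protocol and had a log2 ratio of 5.18 with molecules overlapping at least 50% of the coding sequence. YHR033W (chromosome VIII, 175548 to 176819) was 413-fold higher in the standard protocol (161 to 1518) and 59.0-fold in the long-enriched one (47.7 to 74.0). MRK1 (YDL079C, chromosome IV, 312951 to 314748), a protein kinase of the glycogen synthase kinase 3 family, had 0 and 179 standard reads, 42.9-fold higher with the 0 set to 3 reads (lower limit 34.5). At the lower end stood HXT3 (YDR345C, chromosome IV, 1162957 to 1164660), a low-affinity glucose transporter, with 1405 standard reads in glucose and 1 in galactose (1954-fold lower, 350 to 77227). HXT1 (YHR094C, chromosome VIII, 290913 to 292625) had 362 and 0, 167.8-fold lower with the 0 set to 3 reads (lower limit 135.8). ARG1 (YOL058W, chromosome XV, 219211 to 220473), argininosuccinate synthetase, was 122-fold lower (88.1 to 173). ARG3 (YJL088W, chromosome X, 268799 to 269815) was 181-fold lower (31.9 to 7195), and ARG4 (YHR018C, chromosome VIII, 140011 to 141402) was 9.25-fold lower (7.47 to 11.6). IMD2 (YHR216W, chromosome VIII, 554396 to 555967), an inosine monophosphate dehydrogenase, was 79.96-fold lower (21.6 to 668). MIG2 (YGL209W, chromosome VII, 95858 to 97006), a repressor of glucose-repressed genes, was 45.9-fold lower (23.8 to 101). ARI1 (YGL157W, chromosome VII, 209006 to 210049), an aldehyde reductase, was 45.5-fold lower (33.1 to 64.2) and 17.3-fold lower in the long-enriched protocol, and FET4 (YMR319C, chromosome XIII, 912880 to 914538), a low-affinity iron transporter, was 10.8-fold lower (5.89 to 21.6).

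The gene lists described next were fixed before the data were examined. A list's median log2 ratio is set against 10000 random lists of the same size matched on mean expression, as a description of these columns. The random lists were drawn with replacement from all measured genes of like expression, the list's own members included. All 7 measured members of the galactose pathway were higher (median 12.04, or 9.45 with zeros set to 3 reads, percentile 100). Of the 4 other reported Gal4 targets, 3 were higher. GCY1 (YOR120W, chromosome XV, 551114 to 552052), a glycerol dehydrogenase, had 21 and 4358 reads and was 149-fold higher in the standard protocol but 5.60-fold higher in the long-enriched one (4.86 to 6.48). Its mean standard 5' UTR was 502 nt in glucose and 44.6 nt in galactose, so both folds compare molecules of unlike length. Whether this sets the difference between protocols was not tested. MTH1 (YDR277C, chromosome IV, 1014401 to 1015702), a repressor of hexose transporter genes, was 14.0-fold higher (10.1 to 20.0), and PCL10 (YGL134W, chromosome VII, 255663 to 256964), a cyclin that acts on glycogen synthase, 3.65-fold higher (2.99 to 4.50). FUR4 (YBR021W, chromosome II, 281443 to 283344), the uracil permease next to GAL1, was 2.15-fold lower (1.22 to 3.86); under scaling by total reads its log2 ratio was -0.61 and the call was lost, and it turned to 0.25 when molecules overlapping at least 50% of the coding sequence were counted.

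Among sugar transport and glycolysis genes most members that passed the threshold were lower. Of 5 measured hexose transporter genes, HXT1, HXT2, HXT3 and HXT4 were lower and HXT7 was higher, and the list's median log2 ratio was -5.61 (percentile 0). HXT2 (YMR011W, chromosome XIII, 288079 to 289704) had 664 and 65 standard reads and was 14.2-fold lower, HXT4 (YHR092C, chromosome VIII, 287081 to 288811) had 52 and 1 standard reads, and HXT7, whose coding sequence has a near-identical copy, had 103 and 750. Of 19 measured genes of glycolysis and ethanol fermentation, 8 were lower, 3 higher and 8 neither (median -1.51, percentile 0). TDH2 (YJR009C, chromosome X, 453683 to 454681), a glyceraldehyde-3-phosphate dehydrogenase with near-identical copies, was 8.71-fold lower (8.51 to 8.92), and GPM1 (YKL152C, chromosome XI, 163642 to 164385), phosphoglycerate mutase, was 3.51-fold lower (3.48 to 3.55). The 3 that were higher were HXK1, GLK1 and PYK2. HXK1 (YFR053C, chromosome VI, 253592 to 255049), hexokinase, was 17.6-fold higher (12.7 to 25.2) and GLK1 (YCL040W, chromosome III, 50838 to 52340), glucokinase, 3.79-fold higher (3.21 to 4.49) and 8.01-fold (7.42 to 8.67) in the long-enriched protocol.

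Respiratory genes were higher as a group. All 34 measured genes of the respiratory chain and ATP synthase were at least 2-fold higher (median log2 ratio 2.00 in the standard and 2.14 in the long-enriched protocol, percentile 100 in both). INH1 (YDL181W, chromosome IV, 135179 to 135436), the ATP synthase inhibitor, was 9.25-fold higher (8.31 to 10.3) in the standard and 5.02-fold (4.19 to 6.05) in the long-enriched protocol, RIP1 (YEL024W, chromosome V, 107260 to 107907), the Rieske protein of complex III, was 7.24-fold higher (6.12 to 8.62), QCR8 (YJL166W, chromosome X, 106434 to 106718) was 7.06-fold (6.18 to 8.08) and 3.86-fold (3.09 to 4.87) higher in the same order, and QCR6 (YFR033C, chromosome VI, 224326 to 224769) was 6.86-fold higher (6.02 to 7.86). Of 15 measured genes of the tricarboxylic acid cycle, 10 were higher and 5 neither (median 1.55, percentile 100). SDH2 (YLL041C, chromosome XII, 53131 to 53931) was 7.94-fold higher (5.27 to 12.5), SDH4 (YDR178W, chromosome IV, 817950 to 818495) 5.88-fold (5.53 to 6.26), CIT1 (YNR001C, chromosome XIV, 629622 to 631061), citrate synthase, 5.21-fold (4.30 to 6.35) and MDH1 (YKL085W, chromosome XI, 279123 to 280127), malate dehydrogenase, 5.09-fold (4.83 to 5.37). Of 62 measured members of the fixed list of mitochondrial ribosomal proteins, 5 passed the 2-fold threshold and 57 did not. Still, all 62 log2 ratios were above 0 in the standard protocol (median 0.75, percentile 100). MRPL4 (YLR439W, chromosome XII, 1014491 to 1015450) was 2.40-fold higher (1.88 to 3.10) and MRPL25 (YGR076C, chromosome VII, 637104 to 637577) 2.37-fold (1.87 to 3.02); MRPL32 and MRP8 were 2.26-fold and 2.23-fold higher. MRPL4 lost its call with molecules overlapping at least 50% of the coding sequence (log2 ratio 1.26 to 1.21), and MRPL32 with pairs seen at least 2 times (1.17 to 1.21).

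Of 135 measured cytosolic ribosomal protein genes, 3 passed the threshold, all lower, and 132 did not (median log2 ratio -0.58, percentile 0.16, where the random lists had a median of -0.43). Those random lists could themselves draw cytosolic ribosomal protein genes. RPL18B (YNL301C, chromosome XIV, 63570 to 64562) was 2.77-fold lower (2.69 to 2.84), RPL7B (YPL198W, chromosome XVI, 173152 to 174702) 2.17-fold (2.10 to 2.25) and RPS2 (YGL123W, chromosome VII, 277617 to 278381) 2.14-fold (2.12 to 2.15). Under scaling by total reads none of these 3 stayed past 2-fold and the list median was -0.11. The coding lengths of RPL18B and RPL7B, 561 and 735 nt, are shorter than the stretch from start to stop codon. The search for near-identical copies, which included introns, could have missed copies of these genes. Of 46 measured ribosome biogenesis genes none passed the threshold. Their median log2 ratio was -0.47 (percentile 0) and turned to 0.01 under scaling by total reads. Among them GAR1 (YHR089C), a component of box H/ACA particles, had a log2 ratio of -0.92 and NHP2 (YDL208W) of -0.37, which turned to 0.10 under that scaling.

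The lists for other carbon sources and reserves contained fewer measured members. Of 4 measured genes of sucrose and maltose use, MAL33, MAL31 and SUC2 were higher (median 2.93, percentile 100), with SUC2 (YIL162W, chromosome IX, 37385 to 38983), invertase, at 6.08-fold (3.25 to 12.6), MAL33 (YBR297W, chromosome II, 800523 to 801929) at 11.4-fold (5.35 to 29.0) and MAL31 (YBR298C, chromosome II, 802631 to 804475), with 2 standard reads in glucose, at a ratio of 12.2 (3.13 to 105). With molecules overlapping at least 50% of the coding sequence the log2 ratio of SUC2 went from 2.55 to 0.27, without a call, and the list median to 1.24. Of 5 measured genes of gluconeogenesis and the glyoxylate cycle, JEN1 and ADH2 were higher (ADH2 with a log2 ratio of 2.004 but no call when only pairs seen at least 2 times were counted), CIT2 was lower (log2 ratio -0.93 under scaling by total reads and -0.95 with molecules overlapping at least 50% of the coding sequence, without a call in either) and 2 were neither (median 1.88, percentile 99.7). JEN1 (YKL217W, chromosome XI, 22234 to 24084), the lactate permease, had 0 reads in both glucose columns and 26 and 202 in the galactose columns. Of 9 measured genes of trehalose and glycogen, 5 were higher (median 1.56, percentile 100), among them GLC3 (YEL011W, chromosome V, 133120 to 135234), the glycogen branching enzyme, at 9.53-fold (3.51 to 36.3) and GSY2 (YLR258W, chromosome XII, 660716 to 662833), glycogen synthase, at 3.13-fold (2.03 to 4.99). Of 23 measured heat shock and general stress genes, 4 were higher, 1 was lower and 18 were neither (median 0.41, percentile 99.0). DDR2 (YOL052C-A, chromosome XV, 231570 to 231755) was 12.4-fold higher (7.39 to 22.5), and SSA2 (YLL024C, chromosome XII, 95566 to 97485), an Hsp70 chaperone with a near-identical copy in SSA1, was 4.28-fold lower (4.10 to 4.46).

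Of 9 measured genes of the iron regulon, 6 were higher and none lower (median 1.87, percentile 100). FIT3 (YOR383C, chromosome XV, 1060441 to 1061055) and FIT2 (YOR382W, chromosome XV, 1059531 to 1059992), cell wall mannoproteins that retain siderophore iron, were 57.5-fold (45.6 to 73.4) and 18.1-fold (15.2 to 21.7) higher in the standard protocol, and FIT3 15.6-fold (11.4 to 22.0) in the long-enriched one. TIS11 (YLR136C, chromosome XII, 415801 to 416658), a protein that promotes decay of mRNAs under iron shortage, was 10.2-fold higher (4.98 to 24.1). Of 5 measured genes of the phosphate regulon, PHO89 and PHM6 were higher and 3 were neither, and the median of 0.57 lay within the range of the random lists (percentile 96.0). PHM6 (YDR281C, chromosome IV, 1022007 to 1022321) was 2.73-fold higher (2.23 to 3.36). None of 3 measured stationary phase genes passed the threshold (median 0.63, percentile 82.7); YGP1 had a log2 ratio of 0.63 and SNZ1 of -0.32, or 0.16 under scaling by total reads. Only 1 of 17 haploid and mating type genes was measured in these diploid cells, GPA1, with a log2 ratio of 1.11 and no call. Only 1 of 17 meiosis and sporulation genes was measured, SPS4, which was 3.90-fold higher (2.19 to 7.48), while IME1 had 6 and 6 standard reads.

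The pair of ends places each molecule at the GAL7, GAL10, GAL1 and FUR4 region of chromosome II. In galactose 24292 standard reads covered GAL1 alone, and 10 standard and 31 long-enriched reads covered GAL1 and FUR4 in 1 molecule, starting between 278952 and 278966 and ending between 283430 and 283531. In glucose no read covered both. Molecules covering GAL10 and GAL7 together numbered 1, in the long-enriched galactose column. On the strand opposite to GAL10, 18 reads started inside its coding sequence in the capped glucose columns, 2 of them standard (interval 0.24 to 7.22) and 16 long-enriched (9.15 to 26.0), and 0 in the capped galactose columns, whose upper limit is 3.69 in each. Of these 18 reads, 16 started between 276738 and 276837, near the 3' end of GAL10, and spanned 1312 to 2194 nt; this grouping of 5' ends was made after they were seen, and 4 of the 18 reads remained when only pairs seen at least 2 times were counted. The depth-scaled galactose over glucose ratio had an upper limit of 0.21.

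**Figure D2:**
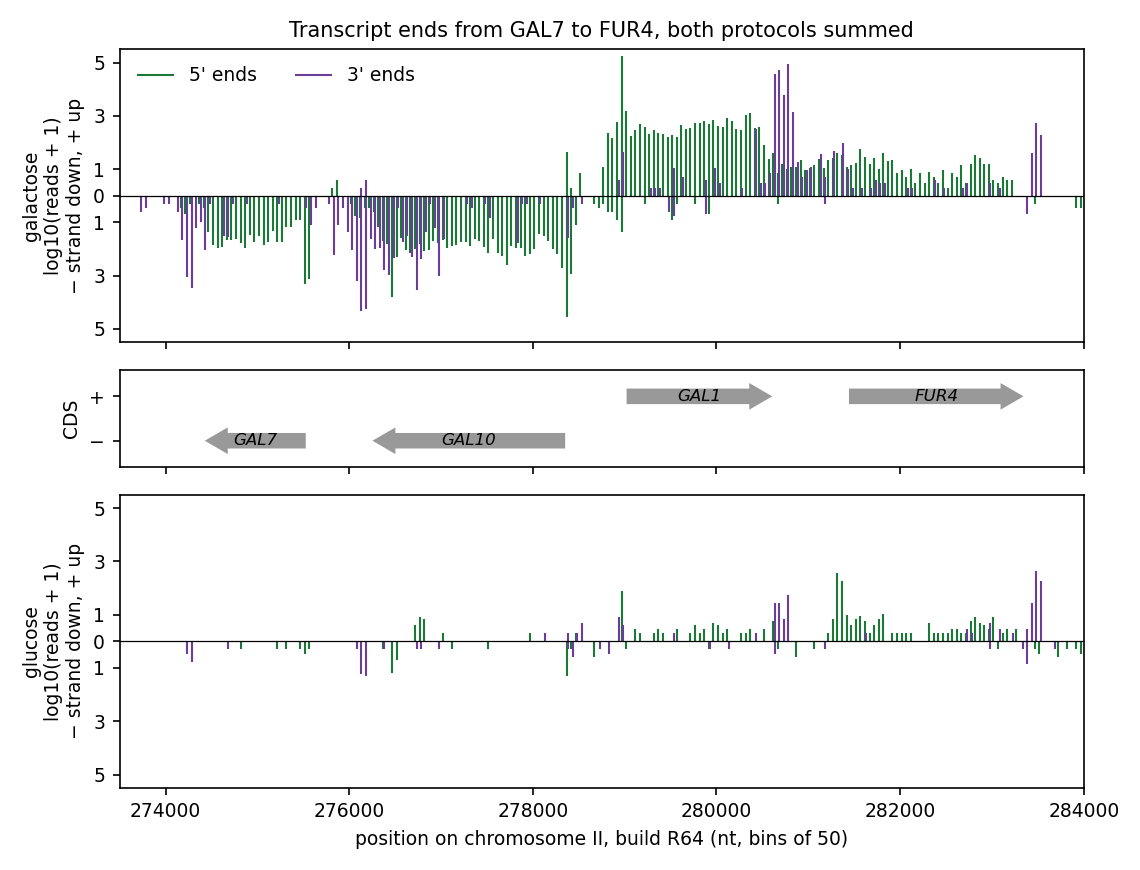
Reads per 50-nt bin of 5' ends (green) and 3' ends (purple) on chromosome II of build R64, + strand upward and - strand downward as log10 of reads plus 1, standard and long-enriched reads summed, with coding sequences as arrows. In galactose the ends sit at the GAL genes, and in glucose 16 reads of the + strand start between 276738 and 276837 inside GAL10.

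The next question was whether the medium shifts where transcripts begin and end. Among 2666 genes with at least 20 covering reads in each of the 4 capped columns, 30 had a mean 5' UTR at least 20 nt longer in galactose in both protocols and 34 at least 20 nt shorter. With the reads of both media dealt at random 20 times, at most 10 genes were longer and at most 6 shorter; with at least 50 reads, where no deals were made, 13 were longer and 13 shorter. GCY1 had a mean 5' UTR of 502 nt in glucose (standard error over reads 49.6, 21 reads) and 44.6 nt in galactose (0.35, 4358 reads), and 576 and 62.1 nt in the long-enriched columns. GAL80 went from 76.7 nt (3.07, 58 reads) to 18.8 nt (1.20, 310 reads), and from 73.2 to 25.5 nt in the long-enriched columns. In the opposite direction FUR4 was at 99.1 nt (4.10, 34 reads) in glucose and 580 nt (87.6, 22 reads) in galactose, with 96.4 and 468 nt in the long-enriched columns. The galactose mean of FUR4 is not the position of a start site, because its 5' ends were spread. Of the 22 standard reads, 22.7% lay in each of the bins that start at 200 and 1050 nt. Reads covering FUR4 alone started as far upstream as 279248, inside the coding sequence of GAL1. FUM1 (YPL262W, chromosome XVI, 47336 to 48802), fumarase, which has mitochondrial and cytosolic forms, was at 32.7 nt (6.93, 62 reads) and 112 nt (5.16, 219 reads), with 61.0 and 139 nt in the long-enriched columns.

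**Figure D3:**
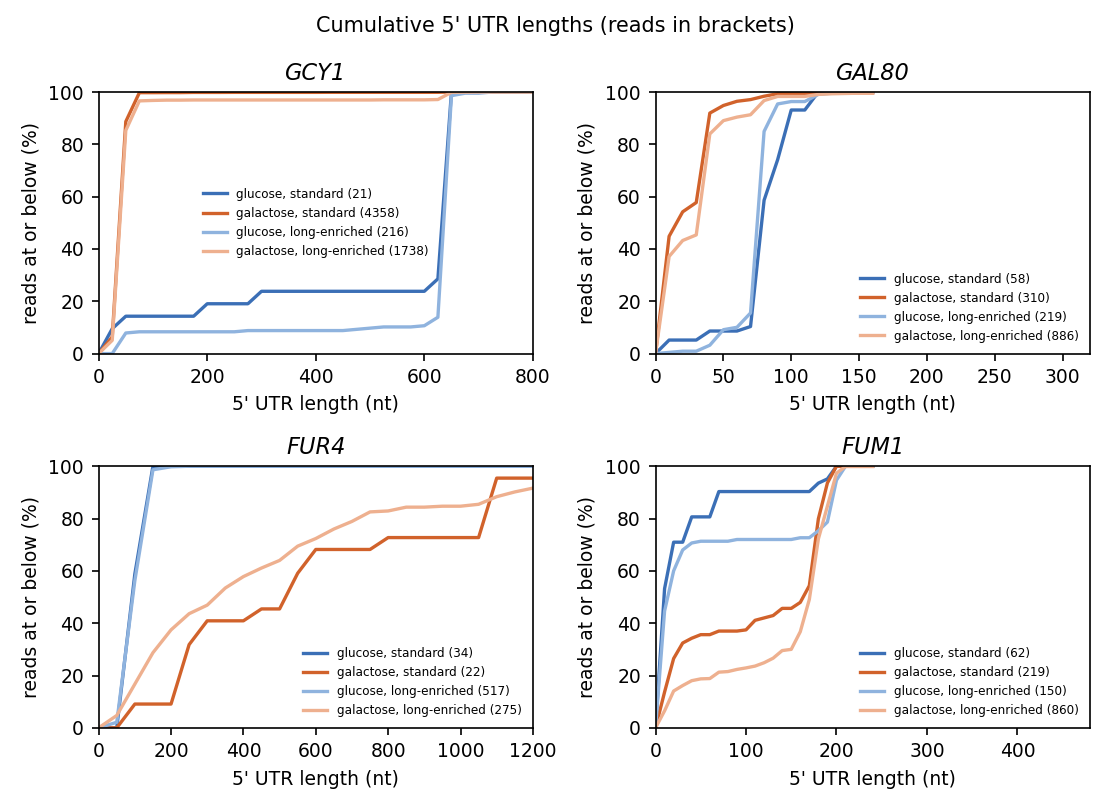
Cumulative share of reads by 5' UTR length in nt for GCY1, GAL80, FUR4 and FUM1, a line per column with its number of reads. In glucose 71.4% of the standard GCY1 reads had a 5' UTR in the bin that starts at 625 nt, and in galactose 82.4% were in the bin that starts at 25 nt.

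Other 5' shifts were smaller or rested on fewer reads. LPX1 (YOR084W, chromosome XV, 480587 to 481750), a peroxisomal lipase, was at 357 nt in glucose and 187 nt in galactose, and the median shift was -299 nt in the standard protocol, though the rule for both protocols was then not met. CSS2 (YFR020W, chromosome VI, 192737 to 193435) was at 310 and 560 nt. MIN6 (YBL039W-B, chromosome II, 143393 to 143572) was at 232 and 187 nt. PAU23, TDA6 and IGO1 had shifts of 139, 68.6 and -53.8 nt by the mean, and of 13, 0 and 0 nt by the median. Over all covering reads, and so weighted by expression, the median 5' UTR was 31 nt in glucose and 35 nt in galactose, while over genes the median of the means was 43.6 and 43.7 nt and the median shift 0.39 nt.

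For 3' ends, 4 genes were at least 20 nt longer in galactose in both protocols and 31 shorter, against at most 10 and 10 in the random deals, so the 4 longer genes were no more than counting error gives. The shorter genes numbered 16 without UTRs over 500 nt and 10 with at least 50 reads, settings for which no random deals were made. SNM1 (YDR478W, chromosome IV, 1414575 to 1415171), a component of RNase MRP, had a mean 3' UTR of 398 nt in glucose (standard error over reads 71.0, 30 reads) and 174 nt in galactose (35.1, 39 reads). ASI2 (YNL159C, chromosome XIV, 338478 to 339347), an inner nuclear membrane protein, was at 426 nt (25.9, 54 reads) and 339 nt (20.2, 61 reads), without a call when UTRs over 500 nt were left out. BTT1 (YDR252W, chromosome IV, 963412 to 963861) was at 677 and 604 nt, MMM1 at 303 and 67.2 nt, and RRG7 at 229 and 152 nt; by the median these 3 shifts were -42, -2 and -2 nt. The 4 longer genes, SGF29, YGL159W, ANY1 and TCA17, had median shifts of 0, 0, 16 and 0 nt. The median 3' UTR over reads, which is weighted by expression, was 106 nt in glucose and 111 nt in galactose, while over genes the median of the means was 121.7 and 119.5 nt and the median shift -1.03 nt in the standard and -1.70 nt in the long-enriched protocol.

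The number of isoforms, meaning distinct pairs of ends, was compared at an equal depth of 50 reads per gene. Equal depth does not remove that the glucose column pools 2 cultures and the galactose column 4, or that duplicate reads may not have been collapsed. Over 2305 genes the median was 29.4 isoforms in glucose and 30.1 in galactose, and the median difference was 0.30 (bootstrap interval over genes 0.22 to 0.40). With ends binned to 5 nt this difference was 0.067, and over the 1787 genes measured in both protocols it was 0.08 in the standard and 0.22 in the long-enriched one. By the mean of the media COA6 (YMR244C-A), a cytochrome oxidase assembly factor, had the most, 42.5 in glucose and 44.3 in galactose, followed by RPS4A with 43.5 and 43.0, TOM40, the pore of the outer mitochondrial membrane, with 43.7 and 42.4, RPL2A with 42.4 and 43.6, and APT2 with 42.9 and 43.1. TDH3 (YGR192C), the main glyceraldehyde-3-phosphate dehydrogenase, had 9.71 and 9.18 and TEF1 (YPR080W), a translation elongation factor, 9.40 and 9.71, with 368945 and 30937 standard reads in glucose. RPS26A had 11.05 and 10.68, NTG1, with 51 reads in glucose, 10.9 and 10.9, and VAM3, with 50, 11 and 12.2.

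Molecules were then sorted by what they cover. Those covering 1 whole coding sequence made up 91.9% of standard reads in glucose and 89.8% in galactose, a difference of -2.07 percentage points (interval -2.11 to -2.04), and 89.4% and 89.2% of long-enriched reads. Molecules lacking the 5' part of a coding sequence were 5.99% and 7.54%, a difference of 1.55 points (1.52 to 1.57), which was 0.20 points (0.17 to 0.24) in the long-enriched protocol. In galactose GAL1 and GAL10 supplied 9687 and 7242 standard reads of this class. Molecules lacking the 3' part were 0.77% and 0.94% of reads but 2.88% and 2.69% of distinct pairs, and those lacking both parts 0.10% and 0.14%. Molecules on the strand opposite to a coding sequence were 0.40% and 0.42% in the standard protocol and 0.53% and 0.44% in the long-enriched one, so that by reads galactose was higher in the former and lower in the latter; by distinct pairs it was lower in both, with 2.52% and 2.06%, and 2.16% and 1.71%. Molecules overlapping no coding sequence were 0.76% and 1.06%, and 0.72% and 0.68% in the long-enriched protocol, again in opposite directions. The intervals of these class differences, of 0.30 points (0.29 to 0.31) for the last class, are narrow because of the depth and do not cover differences between cultures.

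Molecules covering 2 or more coding sequences were 0.10% of standard reads in glucose, 0.11% in galactose, and 0.32% and 0.31% of long-enriched reads. Examples are named by the coding sequence that they overlapped most, and the size of the other frame was not examined. CPA1 (chromosome XV, 882899 to 884134), a subunit of carbamoyl phosphate synthetase with an annotated upstream frame, was covered together with another frame in 1454 long-enriched glucose reads and alone in 133. NSG2 (chromosome XIV, 341069 to 341968) had 329 such standard reads in glucose and 598 in galactose, and HST1 (chromosome XV, 200368 to 201879), a histone deacetylase, 521 and 645 long-enriched reads.

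The long-enriched protocol was compared with the standard one to see which molecules it adds. Among molecules covering 1 coding sequence, the median span was 904 nt in glucose and 868 nt in galactose with the standard protocol, and 1512 and 1576 nt with the long-enriched one, a difference of 608 and 708 nt. Spans over 1500 nt made up 4.99% and 6.09% of standard reads and 51.3% and 57.8% of long-enriched reads. Of 4159 genes measured in this comparison, 1740 were at least 2-fold higher with the long-enriched protocol in both media and 1604 at least 2-fold lower. Their median coding lengths were 1778 and 639 nt. Under scaling by total reads 1998 genes were higher and 481 lower. For coding lengths from 2000 to 2500 nt, 40.1% of genes had at least 10 standard reads in glucose and 83.0% had at least 10 long-enriched reads, although the standard column was deeper. Above 4000 nt, 0 of 240 genes reached 10 standard reads and 8 reached 10 long-enriched reads in glucose. SLI15 (YBR156C, chromosome II, 551104 to 553200), a subunit of the chromosomal passenger complex, had 1 standard and 54 long-enriched reads in glucose, and 1 and 88 in galactose. DPH6 (YLR143W, chromosome XII, 427329 to 429386) had 6 and 226 reads in glucose, and VPS36 (YLR417W, chromosome XII, 955010 to 956710), an endosomal sorting protein, 4 and 130. DUG2 (YBR281C) had 1 and 65, and NAM7 (YMR080C), a helicase of nonsense-mediated decay, 2 and 102. In the other direction PGK1 (YCR012W, chromosome III, 137746 to 138996), phosphoglycerate kinase, had 3628 standard and 12 long-enriched reads in glucose although its coding length is 1251 nt. RPL33A had 18951 and 43, RPL21A 12535 and 33, SPO24 1027 and 12, and the small frame YCR024C-B 161 and 1.

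**Figure D4:**
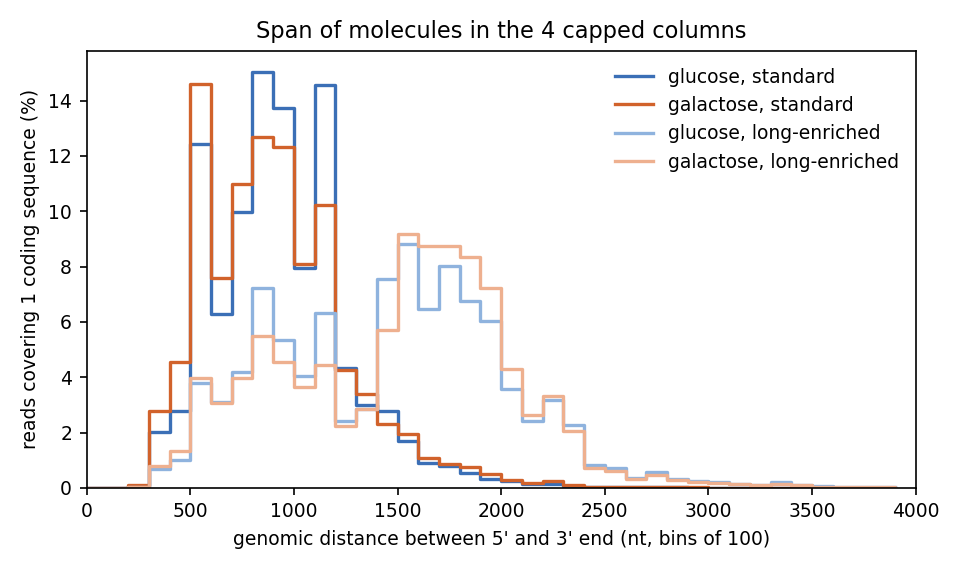
Share of reads covering 1 coding sequence by genomic distance between the ends, in 100-nt bins, for the standard and long-enriched columns of both media. The long-enriched columns have a second group of molecules above 1400 nt, and their medians are 1512 nt in glucose and 1576 nt in galactose.

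The non-capped control asked how far the 5' ends depend on the cap. Within 50 nt of the most used 5' end of the gene, taken from the other capped protocol, lay 91.4% of the standard glucose reads and 90.4% of the standard galactose reads, but 5.78% (exact binomial interval 5.74 to 5.82) and 6.68% (6.63 to 6.73) of the non-capped reads. 5' ends inside a coding sequence were 6.09% and 7.68% of standard reads and 91.6% and 90.2% of non-capped reads. Upstream of the start codon lay 93.7% of the standard glucose reads that overlap a coding sequence and 5.73% of the non-capped ones. The control held abundant transcripts, with TDH3 at 3.26% of the glucose column and RPL3, a ribosomal protein gene, at 3.01%. GAL1 made up 2.22% of the non-capped galactose reads and 0.53% of the standard ones, and had 1 read in the non-capped glucose column. GCN4, the activator of amino acid synthesis genes, was at 1.27% of the non-capped and 0.42% of the standard glucose reads. With 1 library per medium the control has no replicate of its own.

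**Figure D5:**
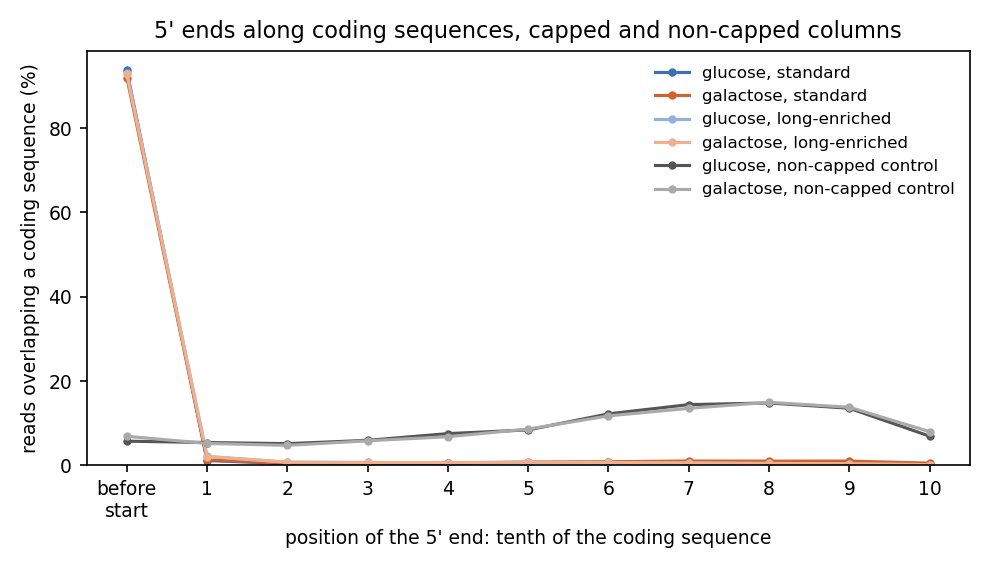
Share of reads overlapping a coding sequence whose 5' end lies before the start codon or in each of 10 equal parts of the coding sequence, a line per column. The capped columns have over 90% of 5' ends before the start codon, with 93.7% in glucose and 92.0% in galactose, while the non-capped columns have 5.73% and 6.89% there.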

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

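The tests on carry-over by shares, on low expression in glucose, on the 8-base site and on ends inside coding sequences were chosen after related results were seen, and only the test on exact pairs of ends was set beforehand. Some results went in opposite directions in the standard and the long-enriched protocol; the difference between protocols was not tested beyond the counting intervals. RPL21A, a ribosomal protein gene on chromosome II, had a log2 ratio of galactose over glucose of -1.01 in the standard and 1.42 in the long-enriched protocol. It had 12535 and 8668 standard reads in glucose and galactose, but 33 and 128 long-enriched ones. For RPL33A, another ribosomal protein gene, the values were -1.22 and 1.40, on 18951 and 11347 standard and 43 and 164 long-enriched reads. The long-enriched protocol thus kept few reads of either gene. How far the carry-over described next affects their long-enriched ratios was not tested. ZPS1, a gene induced by zinc shortage, had -1.39 and 2.44 on 25 and 13 standard and 2 and 19 long-enriched reads. The 5' UTR shift was opposite in the protocols for 13 genes and the 3' UTR shift for 18.

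The long-enriched glucose column held 141 covering reads of GAL1, GAL10 and GAL2. Low expression in all glucose cultures would have given 30.9 such reads in the standard glucose column, with a lower limit of 21.1, and it held 1, which argues against that explanation, although how the 2 glucose cultures, which supplied both columns, split the reads of each is unknown. Carry-over from the long-enriched galactose libraries would make the reads a fixed share of that column over genes and classes, and the chi-square over its degrees of freedom was 66.9, which argues against it too, while a fixed share of 0.30% of the standard galactose column gave 0.956. The pairs of ends of 97.9% of the 141 reads also occur in a galactose column, which decides nothing, since molecules made in glucose could share them and draws from the standard and the long-enriched galactose column had the same median of 99.3%. From the shares, a candidate explanation is carry-over of standard galactose molecules or reads into this column, which at that share would make 0.70% of it, and whose subtraction left 5, 2, 6 and 0 reads of GAL1, GAL10, GAL2 and GAL7 and moved the long-enriched log2 ratios of the former 3 from 10.37 to 14.19, from 10.10 to 12.83 and from 10.14 to 13.04; the share was fitted to these genes, and it does not account for GAL3 (24 reads, 3.5 expected, 20 left) or PHO89 (51, 1.71 and 49).

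Genes whose coding sequence holds the 8-base sequence GCGGCCGC were almost without full-length reads, a sequence picked from a screen of 9 recognition sequences of restriction enzymes, made after the ends inside DLD1 were seen; among coding sequences of 1000 to 2000 nt the 19 genes with it had a median of 0 CPM in both long-enriched columns, against 28.6 and 35.1 in genes without it, and the other 8 sequences had medians of at least 14.4. Over the 29 such genes other than DLD1, 3.39% of capped reads spanned the site (Wilson interval 3.03 to 3.79; 118 of 252 in DCW1), against 95.3% at the same relative position in the 50 genes nearest in coding length to each. Low expression of these genes is argued against, since non-capped reads that do not span the site had a median of 46 per gene against 67 in the other genes, a ratio of 0.687, where the ratio for capped spanning reads was 0.0070. Molecules may have been cut at this sequence during library preparation; no label names such an enzyme, so this stays a hypothesis. In DLD1, a mitochondrial lactate dehydrogenase on chromosome IV with the site at 146553 to 146560, 7409 of 7434 long-enriched galactose reads ended within 20 nt of it but 11 of 164 standard ones did, and in the other genes together 5568 of 8642 capped reads did.

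Molecules ending inside a coding sequence were led in the standard columns by FUN12, with 5567 such reads in glucose against 169 covering reads. Of all reads ending inside a coding sequence, 36.6% were followed by at least 7 A within 10 nt, against 3.09% of positions in the same coding sequences, which is consistent with priming inside A-rich sequence for part of them. In the standard columns the share was 52.5% in glucose and 53.1% in galactose, and in the long-enriched ones 30.4% and 20.7%. Reads covering 1 coding sequence had such a flank in 12.5% and 12.9% of standard and 13.7% and 13.6% of long-enriched reads, so the excess over them was smaller in the long-enriched columns. Pooled over genes, those without an A-rich flank were 1.23 times as frequent in galactose as in glucose in the standard protocol and 1.19 times in the long-enriched one. Both lay within the limit of 1.5 times, which was chosen after the share of this class was seen. A pooled share does not decide whether the medium affects such ends, because it sums over genes whose levels also differ between media. With any flank, long-enriched reads lacking the 3' part numbered 1700 in glucose and 6994 in galactose for DLD1, but 2026 and 871 for PUS1. Such counts can follow the level of the gene. Among covering and 3'-lacking reads of the gene together, the 3'-lacking ones were 99.94% and 99.96% for DLD1. For PUS1 they were 88.36% and 82.25%, so the counts do not show that these ends went both ways. What ends the remaining molecules stays open; SSA1 and DLD1 alone supplied 26.7% of such reads in the long-enriched glucose column.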

How the results depend on the processing

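No paired analysis was possible because the columns sum the replicates. For the same reason the DESeq2 Wald test, each replicate left out in turn, replicate blocks, the fit without a replicate block, each library preparation alone and an estimated set correlation were not run. Scaling by total reads, each protocol alone, subtraction of carry-over and removal of genes with the 8-base site were chosen after the data were seen. Of 365 values of the 73 named genes under alternatives, 350 kept their call or stayed without one, 12 lost the call, 2 gained one and FUR4 turned to 0.246 when partly overlapping molecules counted; among genes without a call NHP2, SNZ1 and IME1 turned to 0.10, 0.16 and 0.0024 with total scaling. The cause was not tested for any result below unless stated.

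For genes in galactose against glucose, 348 were higher and 56 lower with total scaling, 366 and 216 with the standard protocol alone, and 339 higher with the long-enriched protocol alone, where fewer conditions have to be met. Size factors, no minimum of reads, the other counting rules, subtraction of carry-over and removal of site genes stayed within 1.5 times. The ribosome biogenesis median turned to 0.0115 with total scaling, and with partly overlapping molecules the stationary phase (0.2653) and phosphate (0.6235) medians passed the upper limit of the random lists in both protocols; the remaining 45 list values kept theirs. Longer and shorter 5' UTRs numbered 13 and 13 at 50 reads, where fewer genes are tested, and 20 were shorter without UTRs over 500 nt. For 3' UTRs these were 1 and 10, and 2 and 16. The isoform difference was 0.067 with 5-nt bins.

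With distinct pairs, class differences in percentage points were -1.392 for 1 coding sequence, 1.905 for a lacking 5' part, -0.189 (reversed) for a lacking 3' part, 0.0796 for both, -0.4651 (reversed) for the opposite strand and 0.06 for no coding sequence. With pairs seen at least 2 times they were -1.64, 1.138, 0.0262 for both parts, 0.028 for the opposite strand, 0.2744 for none, and -0.0002 (reversed) for 2 or more. The gain in median span was 625 nt in glucose and 725 nt in galactose over all molecules, and 629 and 628 nt over distinct pairs. With total scaling 481 genes were lower in the long-enriched protocol. The windows of 20 and 100 nt set the share of non-capped reads at 2.786% and 9.587% in glucose and 3.488% and 10.25% in galactose by their width. Of the 18 reads opposite to GAL10, 4 remained with pairs seen at least 2 times. Depth limits weakly expressed genes; that 18.1% of coding sequences from 2500 to 3000 nt had at least 10 standard glucose reads, against 69.5% in the less deep long-enriched column, is not set by depth.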

Other observations

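Genes of 3 amino acid pathways, picked after the gene table was seen and not set against other genes, had these values. Of 8 measured genes of arginine synthesis 7 were at least 2-fold lower in both protocols and 0 higher, with a median log2 ratio of -3.0 in the standard and -3.08 in the long-enriched protocol. Beside ARG1, ARG3 and ARG4, ARG7 had 278 standard reads in glucose and 44 in galactose, and ARG8 77 and 16. Of 6 measured genes of lysine synthesis 4 were lower (median -1.87), with LYS20, homocitrate synthase, at 4458 and 1375 reads. Of 6 measured genes of histidine synthesis 4 were lower (median -1.50), with HIS3 at 2413 and 640 and HIS4 at 132 and 37.

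Some transcripts outside coding sequences differed by medium. Reads on the opposite strand or off coding sequences were grouped where neighbouring 5' ends lay within 50 nt, and of 346 groups measured in both protocols 22 were at least 2-fold higher in galactose and 46 lower. The most different lay beside GAL80: molecules starting between 171148 and 171463 on the - strand of chromosome XIII, upstream of GAL80 and running across SUR7, had 0 and 291 standard reads in glucose and galactose and 2 and 791 long-enriched reads. Similar molecules pointing away from GAL3 started between 462803 and 463047 on the - strand of chromosome IV, with 0 and 115 standard reads, and others near GAL2 started between 289467 and 289675 on the - strand of chromosome XII, with 17 and 309. A group upstream of ADR1, an activator of glucose-repressed genes, starting between 894525 and 894813 on the + strand of chromosome IV, had 13 and 607, and one near PHO89 on chromosome II had 1 and 352. The groups named here were picked after their values were seen. Among those lower in galactose, the groups at SNR37, SNR47, SNR3 and SNR8 had 407 and 38, 88 and 8, 65 and 0, and 51 and 4 standard reads. Their long-enriched reads were 158 and 15, 33 and 3, 29 and 1, and 23 and 3. The group at SNR33 had 2144 and 2554 standard reads, a scaled galactose over glucose ratio of 0.86 (0.81 to 0.91). In the long-enriched protocol its ratio was 0.67 (0.59 to 0.76). Small nucleolar RNA genes were not tested as a set. SCR1, the RNA of the signal recognition particle, had 8338 and 8439 standard reads. Its scaled ratio was 0.73 (0.71 to 0.75) in the standard and 0.80 (0.78 to 0.82) in the long-enriched protocol.

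SSA1 ended inside its coding sequence in 17195 long-enriched reads and 16 standard reads in glucose, and in 26157 and 2 in galactose. SNF3, a glucose sensor of the hexose list, holds the 8-base site and had 1 spanning read among 98 capped reads. HNT1, an intron-containing gene on chromosome IV, lacked the 5' part of its annotated coding sequence in 97.8% of its standard glucose reads.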
